A study of Mus musculus with 6 samples.

How the data were processed

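Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts open chromatin and inserts sequencing adapters, in primary cortical cultures of newborn mice. Per the labels, 3 libraries came from floxed Satb2 cultures without Cre (floxed) and 3 from floxed cultures that carried Nes-Cre, a Cre recombinase driven by the Nestin promoter that is active in neural progenitors (Satb2 cKO). Cells were given 5 µM cytosine arabinoside on day 3 in vitro against dividing glia. Activity was silenced with 20 µM NBQX, an AMPA and kainate receptor antagonist, for 16 h from day 13. On day 14 the cultures were stimulated with 50 µM bicuculline, a GABA-A receptor antagonist, for 1 h. From each culture 25000 nuclei were tagmented for 30 min at 37 °C, and libraries were amplified for 11 PCR cycles, per the labels' protocols. Samples were grouped by the genotype in their titles.

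The measurement analysed was a single consensus peak list for the whole series, deposited by the authors as chromosome, start and end of each peak. Per the submitters' processing notes, the mouse build was mm10 and the tools were BWA 0.7.17 (a read aligner), SAMtools 1.1 and Genrich 0.6.1 (a peak caller), with no role or order given. How the 6 libraries were combined, whether reads were shifted for the Tn5 cut, how duplicates and reads with several alignments were treated, and the caller's threshold are not given in the sources used here. The list holds no score, read count or level per peak or per sample. The depth of each library is therefore unknown, no interval that needs depth is given, and the planned test of cKO against floxed per peak was not made. Where such a list includes a region open in a single genotype, it looks like a region open in both. Peaks that a deeper library would add, and regions where reads align to several places, are open limits, so a gene without a peak is described only as having none in this list. Whether the list used here is complete in every region is not known. Other libraries named in the study's design, of chromatin contacts and of SATB2 binding, were not used here.

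Gene positions came from a RefSeq gene table of assembly GRCm38.p6, the assembly that mm10 names. The table gives the outer limits, type and symbol of each gene, and 49599 genes on chromosomes 1 to 19, X and Y were used, 21775 of them protein-coding. Another 340 entries with a start below 3 Mb on chromosomes 1 to 19 or X were left out because such starts are positions on scaffolds. Strand, exons, transcription start sites and sequence were not used here. The planned promoter was therefore replaced by a window of 1 kb on each side of either end of a gene, and a peak that overlapped it by at least 1 bp is called a gene-end peak. Such a peak can lie at the start or at the end of transcription, or belong to a neighbouring gene, and where the annotated range starts upstream of the promoter in use the promoter counts as gene body. Peaks were classed as gene end, gene body or intergenic in that order, and planned classes of exons, introns and untranslated regions were not formed. Motif and GC content were not computed. Positions are given 1-based on mm10.

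Shares of peaks per class were set beside 100 random placements of the same peaks on the same chromosome between its first and last gene. A second set of placements moved each peak by at most 100 kb. Peaks per gene were counted over the gene extended by 10 kb on both sides. The 18 gene lists and 7 gene families, the rule for naming genes and most of the other settings tried were fixed before the data were examined. Each list was compared with 10000 random lists of protein-coding genes of the same size drawn within the 10 deciles of gene length, and its percentile is given with ties split evenly. Genes are not replicates, so no p-value was computed. A list is called above or below where its percentile lay outside the central 95%, that is under 2.5 or over 97.5. Over 25 lists of independently drawn genes, 1.25 would lie outside by chance for each of the 2 measures. A few genes are members of 2 lists, and 1 listed gene (Tf) was not found in the table. Families were formed by symbol prefix and can hold other genes of that prefix. Named genes are the 3 members of each list with the most peaks, the members without a gene-end peak of lists of up to 24 genes where these are 3 or fewer, 13 genes fixed by name, and the 10 protein-coding genes with the most peaks and with the most peaks per kb. Named regions are the 5 widest peaks and the 5 windows of 500 kb with the most peaks.

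Alternatives were windows of 500 bp and 2.5 kb, assignment by the peak's midpoint, an overlap of at least 50% of the peak, ends of protein-coding genes alone, a list without the narrowest 25% of peaks (under 462 bp), other gene windows and random lists without matching. Interval counting was checked against direct enumeration for 300 genes and 300 peaks, with 0 mismatches in each. The comparison of lists by their share with a gene-end peak was tested on simulated peaks at 21519 genes, where 200 genes were drawn to receive a gene-end peak with a chance of 90%. All 10 lists of 20 such genes lay above the central 95% of 2000 random lists, and 5 of 100 lists of other genes lay outside it. The other simulated peaks were placed at random. Random placement gave a gene-end peak at 17.8% of genes, against 64.4% in the list for chromosomes 1 to 19 and X. The simulation therefore covers a large contrast and scattered genes, not smaller contrasts or clustered families. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures drawn in matplotlib 3.10.9.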

Results

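Accessible chromatin was mapped in mouse cortical cultures on day 14 in vitro, after 1 h of bicuculline, in 3 floxed and 3 Satb2 cKO libraries. SATB2 is a DNA-binding protein of the nuclear matrix that upper-layer callosal projection neurons of the cortex require. The design asked how its loss changes accessibility in stimulated cortical neurons. The list analysed is a single consensus for the whole series with no value per library, so the genotypes could not be compared and no replicate error can be given. How the libraries were combined is not given, so what follows describes where listed sites lay, without regard to genotype. The depth of the libraries is unknown.

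The consensus list held 89916 peaks that did not overlap each other. Of these, 89700 lay on chromosomes 1 to 19 and X, where they covered 78.7 Mb, or 3.06% of the sequence between the first and last gene of each chromosome. The median width was 654 bp (quartiles 462 and 1037 bp), and the median gap to the next peak was 12830 bp. Peaks wider than 5 kb numbered 246 and peaks wider than 10 kb numbered 12.

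Gene ends were the class with the largest excess of peaks. Within 1 kb of an annotated gene end lay 19484 peaks, or 21.7%, against a mean of 8.69% over 100 random placements (range 8.42% to 9.04%), a ratio of 2.5. When each peak was moved by at most 100 kb instead, the ratio was 1.99. Gene bodies held 46.5% of peaks, against 43.8% at random (43.4% to 44.3%), and the intergenic share was 31.8% against 47.5% (47.2% to 47.9%). The small gene-body excess turned into a deficit, with a ratio of 0.887, when peaks were moved within 100 kb. The intergenic deficit was smaller under that placement, at 31.8% against 36.7%, a ratio of 0.867 in place of 0.669. Gene-end peaks were wide, with a median of 1291 bp, while peaks in gene bodies had a median of 606 bp and intergenic peaks 566 bp.

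A gene-end peak was present at 13872 of 21775 protein-coding genes, or 63.7%. On chromosomes 1 to 19 and X, where peaks were placed at random, the share was 64.4%, against a mean of 17.8% over the placements. Both ends carried a peak at 12.8% of the genes. The median gene had 2 peaks within its body extended by 10 kb (quartiles 1 and 4), and 20.7% of protein-coding genes had none. Among other gene types, the share with a gene-end peak was 70.7% for 403 tRNA genes, 39.1% for 12639 long non-coding RNA genes and 7.17% for 9854 pseudogenes.

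Genes induced by neuronal activity were examined first because all cultures had been stimulated with bicuculline. No unstimulated library was analysed here, so no peak at these genes can be tied to the treatment. Of 24 immediate-early genes, which are transcribed within minutes of stimulation, 23 had a gene-end peak, and the share of 95.8% lay at percentile 99.995 of random lists of matched gene length, whose median was 58.3%. Their median of 4 peaks per gene was at percentile 100, against a median of 2 over random lists. Fos, an AP-1 subunit, had a peak of 5.24 kb on chromosome 12 from 85471651 to 85476894, which ended 380 bp short of the right end of the gene (85473890 to 85477274) and overlapped the windows around both ends. Arc, a regulator of AMPA receptor trafficking, had 4 peaks with a widest of 5.24 kb. Egr1, a zinc finger transcription factor, had a peak of 8.02 kb at its ends, and Npas4, a neuron-specific activity-dependent transcription factor, had a peak of 8.82 kb. The members with the most peaks were Nr4a3 with 13, the nuclear receptor Nr4a1 with 9 and Egr4 with 7. Egr2 had no peak within 10 kb, and the nearest listed peaks were 336 kb to its left and 161 kb to its right. Whether the list is complete over that stretch is not known. When at least 50% of a peak had to lie inside the window, which peaks of more than 4 kb cannot meet at 1 end, the list fell to percentile 50.3. With the gene body alone, its peaks per gene lay at percentile 57.3.

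Late activity-response genes, which include secreted and synaptic proteins, had a gene-end peak in 20 of 22 cases, or 90.9% (percentile 99.2, random median 68.2%). Their median of 4 peaks per gene lay at percentile 98.2. Bdnf, a neurotrophin, had 10 peaks, the widest of them 7.78 kb at a gene end. Sorcs3 had 20 peaks and Inhba, an activin subunit, had 10. Inhba and the chromatin remodelling gene Baz1a had no gene-end peak, although 10 and 4 peaks overlapped their annotated ranges. The share fell to percentile 97.46 with the 50% overlap rule, and the peaks per gene fell to percentile 83.6 with genes extended by 50 kb.

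**Figure D1:**
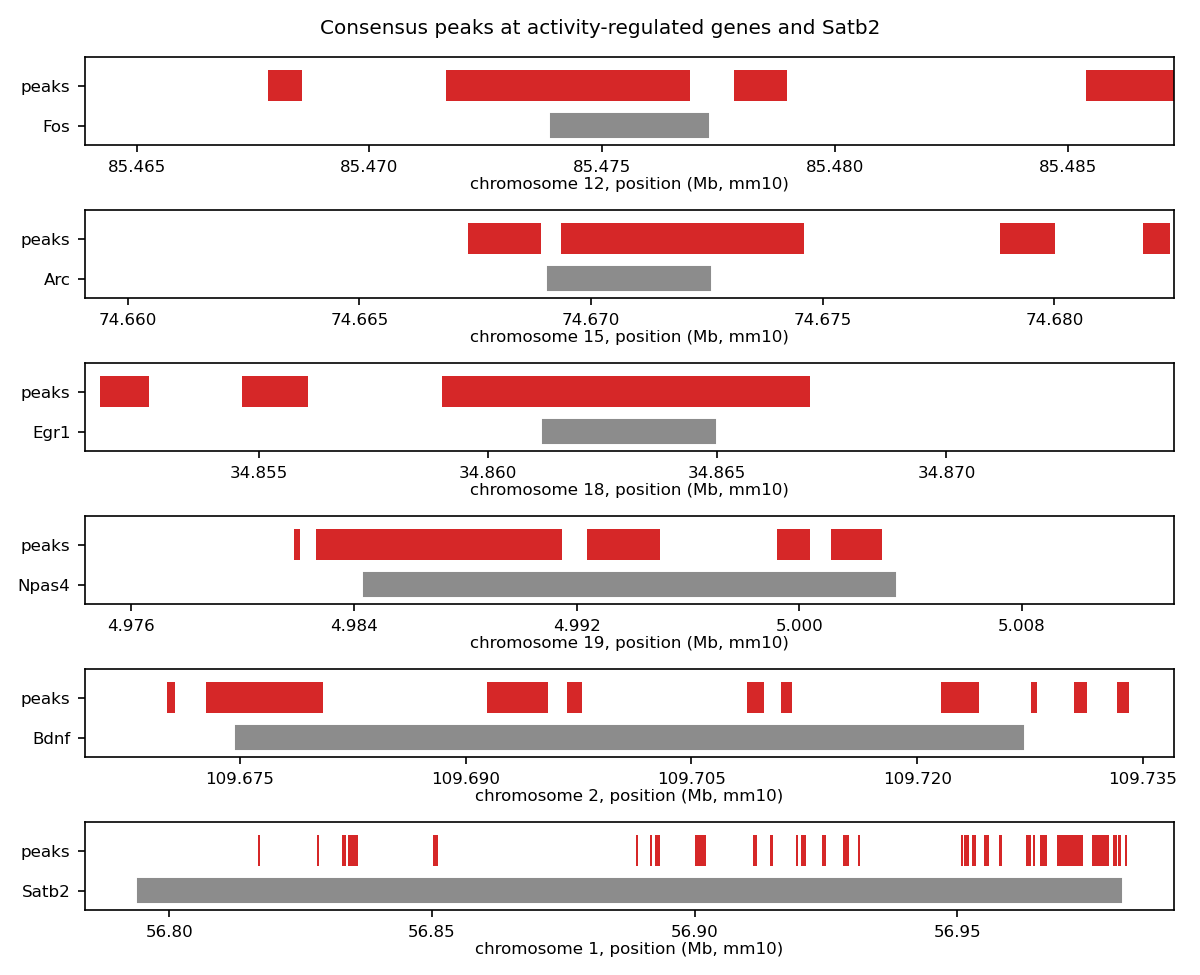
Consensus peaks (red) and annotated gene ranges (grey) on mm10 within 10 kb of Fos, Arc, Egr1, Npas4, Bdnf and Satb2; the horizontal axes give positions in Mb. A single wide peak spans Egr1, wide peaks cover most of Fos and Arc, and Satb2 carries 30 narrower peaks, most of them inside the gene.

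Satb2 itself was rich in accessible sites. The gene spans 187 kb on chromosome 1, from 56793981 to 56981190, and had 30 peaks within 10 kb, 29 of them overlapping the gene. Its widest peak measured 4938 bp and lay inside the gene, while the widest gene-end peak was 678 bp. Satb1, the related chromatin organiser, had 14 peaks over 97.1 kb. The list does not say in which libraries these peaks were open, so they carry no information on the deleted allele.

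Genes of upper-layer callosal neurons, the population marked by Satb2, had many peaks per gene. The median of 11 lay at percentile 99.9, against a median of 5 over random lists of matched length, while the share with a gene-end peak, 17 of 19, lay inside the central 95% (percentile 90.9). Besides Satb2, the members with the most peaks were Cdh13, a cadherin, with 38 and Mef2c, an activity-dependent transcription factor, with 23. Cux2, an upper-layer homeobox gene, had 17. Cdh13 had all of its peaks within its annotated range of 1185 kb and none at a gene end, and Lamp5, with 1 peak, also had no gene-end peak. Of the deep-layer neuron genes, all 19 had a gene-end peak (percentile 99.9), and their median of 7 peaks per gene lay inside the central 95% (percentile 93.5). Sox5 had 49 peaks, Ldb2 had 26 and Bcl11b, a zinc finger gene of corticospinal neurons, had 21. The deep-layer share fell to percentile 96.3 with the 50% overlap rule, and the 2 layer lists were not tested against each other.

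Excitatory neuron genes were called above on both measures, and inhibitory neuron genes were too, though narrowly for the share. All 20 excitatory genes had a gene-end peak (percentile 99.975) and the median was 7.5 peaks per gene (percentile 100), against 3 over random lists. Grin2b, an NMDA receptor subunit, had 44 peaks, Mef2c had 23 and Grin2a had 17. With the 50% overlap rule the share lay at percentile 84.0. Inhibitory neuron genes had a gene-end peak in 18 of 21 cases and a median of 5 peaks per gene (percentile 99.995). The share passed the limit by a narrow margin (percentile 97.535 with ties split) and equalled the upper end of the central 95%, 85.7%. Gad1, which makes GABA, and the homeobox gene Dlx1 had 8 peaks each, and Adarb2 had 18. Pvalb, Vip and Nkx2-1 had no gene-end peak. The inhibitory calls were lost without the narrowest 25% of peaks, at percentile 94.7 for the share and 60.2 for peaks per gene. They were also lost with the 50% overlap rule for the share (93.9) and with 50-kb extensions for peaks per gene (72.0).

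Receptor and synapse lists mostly lay inside the random range. All 9 AMPA and kainate receptor subunit genes had a gene-end peak (percentile 91.2). That share is the highest possible, and the central 95% of random lists also reached 100%. A call above was therefore not possible with this matching. The median was 11 peaks per gene (percentile 73.9), and Grik4 had 25, Grik2 had 18 and Gria2 had 15. GABA-A receptor subunit genes, whose products bicuculline blocks, had a gene-end peak in 12 of 16 cases (percentile 41.0) and a median of 3 peaks per gene (percentile 7.97). Gabrg3 had 23, Gabrb1 had 22 and Gabra5 had 11. Synaptic adhesion genes had a gene-end peak in 22 of 24 cases (percentile 95.5) and a median of 9 peaks (percentile 96.9). With 100 bins of gene length in place of deciles, the random median was 9 peaks as well (percentile 49.5). The members with the most peaks were the neurexin gene Nrxn3 with 62, the teneurin gene Tenm2 with 56 and Cntnap2 with 51. Lrrtm1 had 6 peaks and none at a gene end. Nrxn2 had no peak and lay in a stretch of 684 kb on chromosome 19 without any listed peak, so its value says little about the gene alone. Voltage-gated potassium channel genes had a gene-end peak in 27 of 30 cases (percentile 98.3), which fell to percentile 94.0 with a 500-bp window and to 52.5 with the 50% overlap rule. Their median of 5 peaks per gene lay at percentile 97.0.

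Genes of chromatin architecture, the group to which Satb2 and Satb1 belong, were not richer in peaks than other genes. A gene-end peak was found at 16 of 20 (percentile 64.1). The median of 2 peaks per gene lay at percentile 1.66, below the random median of 3.5, but that call was lost under 6 of 7 other settings, at percentiles from 3.82 to 37.6, and held with 100 bins of gene length (1.17). After Satb2 with 30 and Satb1 with 14, the remodeller gene Chd4 had the most peaks, 6.

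Of 5 lists of other cell types, those of microglia, endothelium and oligodendrocytes had gene-end peaks below the central 95% of random lists, and those of astrocytes and of fibroblasts and pericytes lay inside it. Microglia genes had a gene-end peak in 6 of 19 cases (percentile 0.275), endothelial genes in 7 of 17 (percentile 0.51) and oligodendrocyte lineage genes in 7 of 17 (percentile 0.975). In these lists the most peaks were found at Ptprc (7), Csf1r (6) and P2ry12 (6) for microglia, at Slc2a1 (8), Vwf (8) and Erg (7) for endothelium, and at Mbp (14), Enpp6 (8) and Myrf (5) for oligodendrocytes. Astrocyte genes had a gene-end peak in 13 of 17 cases (percentile 73.6); Nfia had 39 peaks, Slc1a2, a glutamate transporter gene, had 15 and Slc1a3 had 13. With the 50% overlap rule the astrocyte share was 41.2% (percentile 3.75), and with a 500-bp window it was 47.1% (5.87). Gfap, the astrocyte filament gene, had 4 peaks and a gene-end peak of 572 bp. Fibroblast and pericyte genes lay inside the random range with 9 of 15 (percentile 24.4), or 46.7% with a 500-bp window (7.59), and Col1a2 and Pdgfrb had 5 peaks each and Acta2 had 4. The median peaks per gene of these 5 lists lay inside the central 95%, at percentiles 50.8, 41.5, 76.5, 32.1 and 36.6 in the order given. The microglia share lay at percentile 6.37 with a window of 2.5 kb. The oligodendrocyte share moved to between 2.90 and 3.59 under 3 settings, and the endothelial share to 3.52 without length matching.

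Genes of liver and muscle had few gene-end peaks and genes used in every cell had many. Liver genes had a gene-end peak in 4 of 21 cases (percentile 0) and skeletal muscle genes in 7 of 18 (percentile 2.13). The muscle call was lost with a window of 2.5 kb (percentile 5.81) and with the 50% overlap rule (6.44). It was also lost (3.58) without Pygm, which lies in the same peak-free stretch of chromosome 19 as Nrxn2, a test added after the data were seen that could only raise the share. Their medians of 1 peak per gene lay at percentiles 7.32 and 8.98. Alb, the serum albumin gene, had 3 peaks, none of them at a gene end; F2 had 5 and Hnf1a 4. In the muscle list Ryr1, the calcium release channel gene, had 12 peaks without a gene-end peak, and Casq1 and Ckm had 4 each. Housekeeping genes had a gene-end peak in 19 of 20 cases (percentile 99.9) and a median of 3 peaks per gene (percentile 96.5). Tubb5 had 7 peaks, Ppia 5 and Actb 4, and Ywhaz, with 4 peaks, was the member without a gene-end peak.

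Gene families with known tissue restriction had few gene-end peaks. A gene-end peak was found at 38 of 1109 olfactory receptor genes (3.43%), 11 of 352 vomeronasal receptor genes (3.13%), 3 of 39 Hox genes (7.69%) and 13 of 112 genes of the keratin symbol prefix (11.6%), each at percentile 0. Without Krtcap2, Krtcap3 and Krtdap, which are neither keratin nor keratin-associated protein genes, the last was 11 of 109 (percentile 0). Their medians were 0 peaks per gene. Hox genes, which pattern the body axis behind the forebrain, lay at percentile 0.015 on that measure, although this was lost with the gene body alone (4.80) and with gene-end peaks left out (39.8). The other 3 families lay inside the central 95%, at percentiles 50, 2.77 and 8.98. A median of 0 is the lowest possible, and the random medians were 0, 1 and 1. No call below was therefore possible for these 3 with this matching, so lying inside is no sign of a usual number of peaks. With genes extended by 50 kb they lay at percentiles 0, 0 and 0.16. Genes with a ribosomal protein symbol prefix had a gene-end peak in 89 of 100 cases (percentile 100), with a median of 2 peaks per gene (percentile 89.4). That prefix also takes in S6 kinase genes, Rps19bp1 and a few others, and without these 16 genes the values were 80 of 84 (percentile 100) and a median of 3 (percentile 100). Clustered protocadherin genes, which give neurons surface identity, had few gene-end peaks, 25 of 57 (percentile 0), but a median of 11 peaks per gene (percentile 100). Of the 32 members without a gene-end peak, 21 were the genes from Pcdhb2 to Pcdhb22, in a stretch of 378 kb on chromosome 18 without any listed peak. Without these 21, which were left out because they had no peak, the share lay inside the central 95% (percentile 6.29). Members of the alpha and gamma clusters overlap and share ends, so 1 peak counted for many of them, and with each peak assigned to the nearest gene end the list lay at percentile 0 for peaks per gene.

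**Figure D2:**
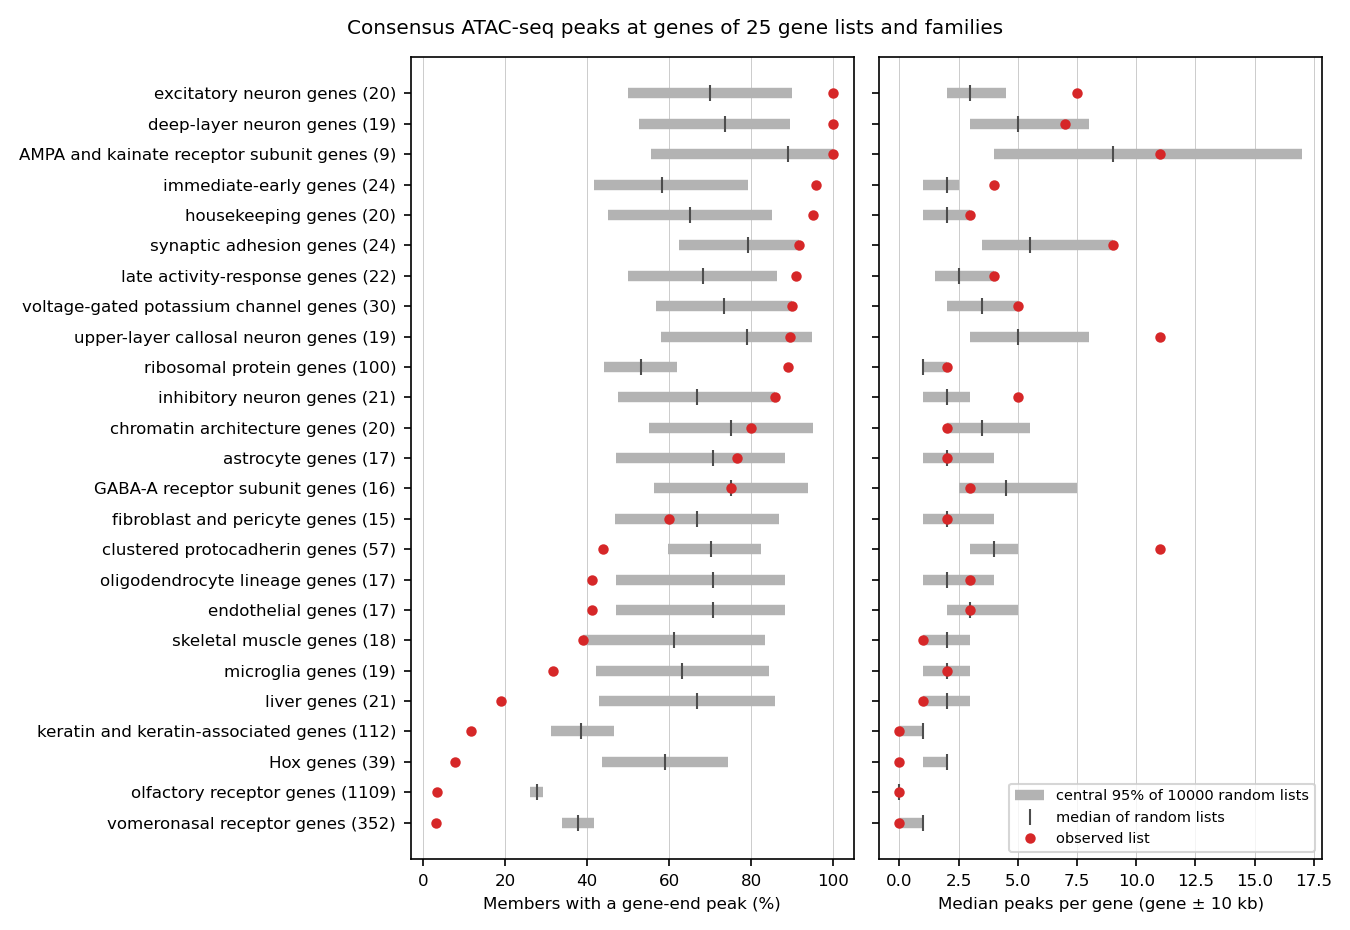
Share of members with a gene-end peak (left, percent) and median peaks per gene within the gene extended by 10 kb (right) for 25 gene lists and families, with the number of genes found in parentheses. Red points are observed lists, grey bars the central 95% and ticks the median of 10000 random lists matched on gene length; excitatory neuron genes and immediate-early genes lie to the right of the bars in both panels, and liver, Hox and olfactory receptor genes lie to the left of the bars on the left panel.

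Over all 25 lists and families, 8 lay above and 10 below the central 95% of random lists for the share with a gene-end peak, and 7 lay inside. For peaks per gene, 6 lay above, 2 below and 17 inside. Some lists inside stood at a bound where no call could be made with this matching. These were AMPA and kainate receptor genes, at the highest possible share, and olfactory, vomeronasal and keratin genes, at the lowest possible median. For lists of independently drawn genes, chance alone would place 1.25 outside for each measure. Members of clustered families such as vomeronasal receptor, Hox and protocadherin genes share peaks or peak-free stretches, and a few genes are in 2 lists. The number to be expected by chance for these lists is therefore not known.

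The protein-coding genes with the most peaks were long, from 345 kb (Tcf4) to 1973 kb (Dlg2), and their counts are not scaled by length. Nav2, a neuron navigator gene, had 98 peaks over 651 kb on chromosome 7. It was followed by Ptprn2 with 86, Iqschfp with 83, Dlg2, a postsynaptic scaffold gene, with 79, and Schip1 with 68. Iqschfp and Schip1 overlap and share peaks. Dab1, of the reelin pathway, had 66, the transcription factor gene Tcf4 had 64, Dlgap1 had 63, and Tenm4 and Nrxn3 had 62 each. Relative to the window searched, short genes led. Nr2f1, a transcription factor gene of cortical area patterning, had 14 peaks, or 0.468 per kb. Gm33099 had 0.340 per kb, Tubb2a 0.337 and Neurod2, a neuronal basic helix-loop-helix gene, 0.330. The windows of Gm33099 and Neurod2 are mostly flanking sequence and overlap on chromosome 11, so peaks in the overlap count for both. Ankrd63 (0.322), Atp1b1 (0.315), Antkmt (0.314), Micos13 (0.314), Egr4 (0.312) and Mdk (0.311) completed the 10.

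The densest windows of 500 kb lay on 4 chromosomes, against a median of 16 peaks among the 4997 windows with a peak. The window from 56000001 to 56500000 on chromosome 17 had 84 peaks and 20 protein-coding genes, Ptprs and Kdm4b among them. A window inside Nav2, from 49000001 to 49500000 on chromosome 7, had 83. On chromosome 17 from 13000001 to 13500000, where Smok2a, Smok2b, Tcp10b and Tcp10c lie, there were 75 peaks. The window from 27500001 to 28000000 on chromosome 15 had 73 peaks. Trio, a guanine nucleotide exchange factor gene, had 57 peaks within 10 kb and lies mostly in that window. On chromosome 8 the window from 84500001 to 85000000, which holds Cacna1a, Junb and Ier2, had 70.

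Peak density was even over the autosomes and low on X. Autosomes had 36.6 peaks per Mb, from 30.0 on chromosome 16 to 41.8 on chromosome 13, and X had 10.4, a ratio of 0.283. The ratio was 0.400 for gene-end peaks and 0.25 for all others. Of the protein-coding genes on X, 46.8% had a gene-end peak, against 65.3% on autosomes and 53.2% on the lowest autosome. Gene-end peaks on X were not narrower than on autosomes, with medians of 1350 and 1289 bp, while other peaks on X were narrower, with 505.5 bp against 589 bp.

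**Figure D3:**
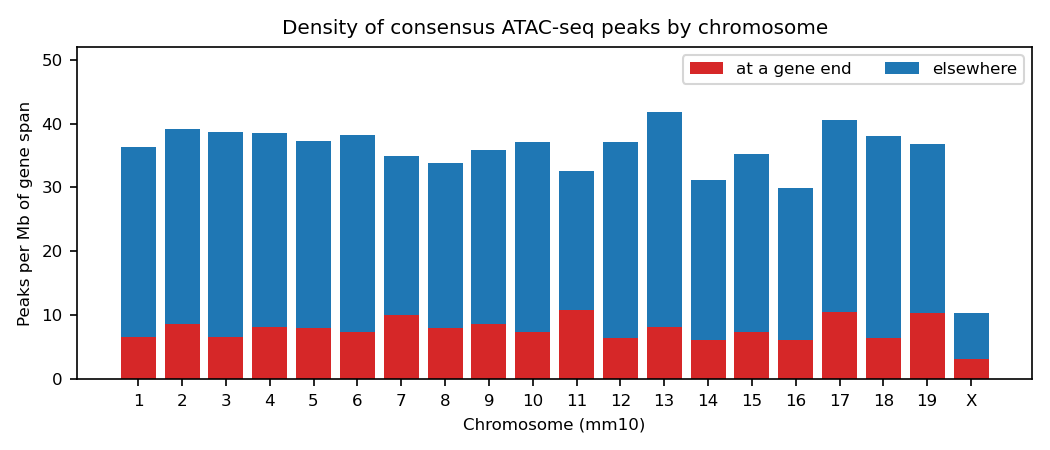
Peaks per Mb between the first and last gene of each chromosome, split into gene-end peaks (red) and all others (blue), with bars stacked from 0. X, at 10.4 peaks per Mb, lies below every autosome, the lowest of which has 30.0.

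The widest peak measured 53.8 kb, on chromosome 1 from 88216553 to 88270366, over the ends of the Ugt1a genes, which encode UDP-glucuronosyltransferases, all of Mroh2a and part of Hjurp, a histone chaperone gene. Peaks of 20.2 kb starting in Hjurp and of 15.6 kb reaching into Trpm8, a cold-sensing channel gene, lay next to it. The others among the 5 widest were a peak of 18.4 kb on an unplaced scaffold and one of 16.0 kb on chromosome 11, from 3184124 to 3200108, in Sfi1.

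**Figure D4:**
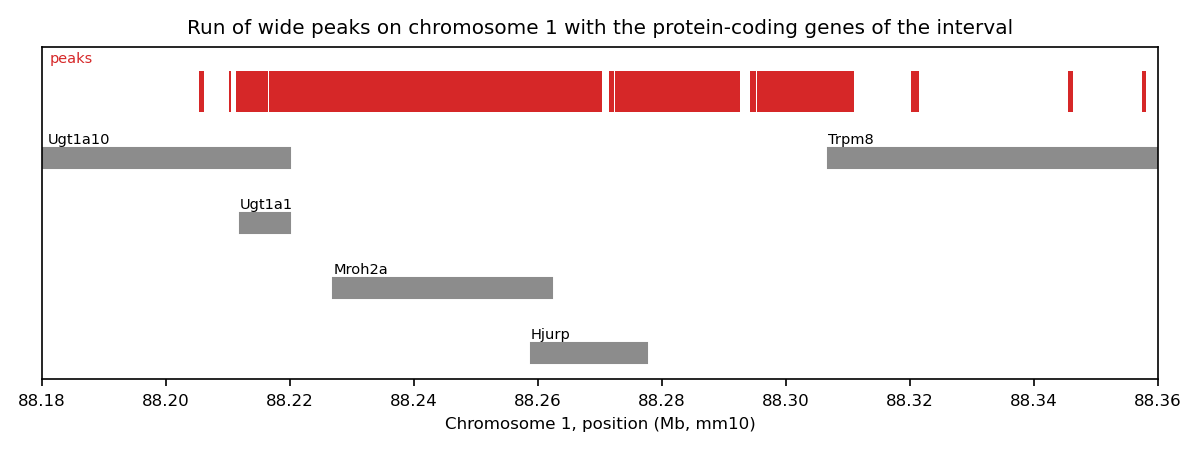
Consensus peaks (red) and annotated ranges of Ugt1a10, Ugt1a1, Mroh2a, Hjurp and Trpm8 (grey) on chromosome 1, with position in Mb on mm10; other Ugt1a genes that share the right end of Ugt1a10 are not drawn. Peaks cover 96.2% of the 101 kb from 88210209 to 88310933, across genes and the sequence between them.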

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

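The tests in this part were chosen after the results were seen. Outside the chromosomes and the mitochondrial genome, 194 peaks lay on 43 scaffolds, sequence that no comparison above used. The mitochondrial genome had 2 peaks. No library without tagmented chromatin was analysed here as a background for either.

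The run of wide peaks on chromosome 1 held 7 peaks over 101 kb, with gaps under 2000 bp. Whether broad accessibility at active genes is its cause could not be decided. Outside the run the widest gene-end peak of any protein-coding gene was 14.1 kb (at Foxg1, a forebrain transcription factor gene). The peak of 16.0 kb in Sfi1 was not such a gene-end peak. The widest peak of the run was 53.8 kb, but the run was chosen for that width, so narrower peaks elsewhere were fixed by the choice. Gene activity was not measured, and a locus unlike all others is not excluded. Extra copies of the interval in these mice, or a repeat that the assembly holds in too few copies, stay open. Peaks covered 95.2% of the intergenic part, but the run was chosen for its coverage and could not have come below 89.3%, so this and a cause particular to the locus cannot be told apart without read depth.

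Chromosome X had 0.283 times the peaks per Mb of the autosomes. Low gene density as the whole cause is argued against by chromosomes 12, 18 and 1, the autosomes closest to X in genes per Mb, since X had 0.285 times the peak density of the lowest of them. Lower read depth from fewer X copies may contribute. Gene-end peaks, which are the wider class, were not narrower on X, at 1.05 times the autosomal median width, while other peaks were, at 0.858 times. Per Mb, the ratio to autosomes was 0.400 for gene-end peaks and 0.25 for other peaks. Lower depth and a property of X chromatin, including X inactivation, cannot be told apart without read counts per library and the sex of the animals, and no biological explanation was tested.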

How the results depend on the processing

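No paired analysis was possible because the list holds peak positions only, with no values per sample, so the planned genotype test, its replicate block and leaving out single libraries were not run. Also not run were the settings fixed beforehand that need sequence, strand or transcripts (motif and GC content, 5 prime-most start sites, nearest start site, lists matched on promoter GC). Assignment to the nearest gene end replaced the nearest start site after the data were seen. For the share of a list with a gene-end peak, 106 of 125 list and setting pairs kept their side of the central 95%, and 8 of 18 called lists did so in every setting applied to all lists (housekeeping, ribosomal protein, liver, olfactory, vomeronasal, Hox, protocadherin and keratin genes). For peaks per gene it was 106 of 150 pairs and 2 of 8 called lists (upper-layer and excitatory neuron genes). Causes were not tested except where stated. The unknown depth limits all absences.

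The share of peaks at a gene end (21.7%) was 18.8% with a 500-bp window, 29.2% with 2.5 kb, 26.2% without the narrowest 25% of peaks, 18.8% by midpoint, 18.8% with at least 50% of the peak inside and 16.1% for ends of protein-coding genes alone, and stayed from 1.85 to 3.75 times the random share. The share of protein-coding genes with such a peak (63.7%) was 60.7%, 68.7%, 62.0% and 57.7% with 500 bp, 2.5 kb, the wider peaks and the 50% overlap. The peak density of X relative to autosomes was 0.258 without the narrowest peaks.

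Percentiles of the share with a gene-end peak that crossed a limit were as follows. The 50% overlap gave 50.3 for immediate-early, 97.46 for late response, 96.3 for deep-layer, 84.0 for excitatory, 93.9 for inhibitory, 3.59 for oligodendrocyte, 6.44 for muscle and 52.5 for potassium channel genes. That rule by construction rejects peaks wide enough to outgrow the window. Lists without length matching gave 99.3 for upper-layer, 99.2 for AMPA and kainate receptor, 99.9 for synaptic adhesion, 3.37 for oligodendrocyte and 3.52 for endothelial genes. Without the narrowest peaks, inhibitory genes lay at 94.7. A 500-bp window gave 97.9 for synaptic adhesion and 94.0 for potassium channel genes, and 2.5 kb gave 2.90 for oligodendrocyte, 6.37 for microglia and 5.81 for muscle genes. In tests added after the data were seen, synaptic adhesion genes lay at 98.9 without Nrxn2, muscle genes at 3.58 without Pygm and protocadherin genes at 6.29 without the 21 Pcdhb genes that had no peak. Leaving out genes without a peak could only raise these shares. The synaptic adhesion share lay at 14.9 with the 50% overlap, 87.6 with 2.5 kb and 94.1 with 100 length bins.

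Percentiles of peaks per gene crossed a limit more often. The gene body alone gave 57.3 for immediate-early, 98.9 for synaptic adhesion, 23.7 for chromatin architecture, 1.32 for microglia, 0.895 for liver, 1.67 for muscle, 4.80 for Hox and 99.4 for potassium channel genes. Extension by 50 kb gave 83.6 for late response, 72.0 for inhibitory, 1.67 for GABA-A receptor, 14.8 for chromatin architecture, 99.2 for housekeeping, 0 for olfactory and vomeronasal receptor, 99.8 for ribosomal protein, 0.16 for keratin and 99.2 for potassium channel genes. Without length matching, deep-layer and synaptic adhesion genes lay at 100, AMPA and kainate receptor genes at 99.97, chromatin architecture at 37.6, olfactory, vomeronasal and keratin genes at 0 and potassium channel genes at 99.995. By nearest gene end, deep-layer genes lay at 99.985, synaptic adhesion at 100, chromatin architecture at 24.9, astrocyte at 99.8, fibroblast and pericyte at 98.1, muscle at 0.40, ribosomal protein at 99.985 and potassium channel genes at 99.9, and clustered protocadherin genes reversed to 0, since each peak then counts for 1 of the overlapping genes. Without the narrowest peaks, inhibitory genes lay at 60.2, chromatin architecture at 11.3, ribosomal protein at 99.0 and potassium channel genes at 99.9. With gene-end peaks left out, synaptic adhesion lay at 97.7, chromatin architecture at 3.82, Hox at 39.8, ribosomal protein at 99.3 and potassium channel genes at 99.4. Without other genes of their symbol prefix, ribosomal protein genes lay at 100. Matching in 100 length bins, added after the data were seen, kept 45 of 46 pairs over 23 lists on their side for both measures and moved keratin genes to 2.125. Within the central 95% it lowered peaks per gene of lists with long genes, from 96.9 to 49.5 for synaptic adhesion, from 73.9 to 31.2 for AMPA and kainate receptor and from 93.5 to 72.0 for deep-layer genes, so percentiles of such lists near the limit depend on how closely length is matched. It could not be done for olfactory and vomeronasal receptor genes, whose bins held too few other genes.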

Other observations

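All comparisons in this part were chosen after the peaks were seen. Lists also differed in the width of their gene-end peaks. Among the 23 immediate-early genes with such a peak, the median of the widest was 4189 bp, at percentile 100 of random lists of genes with a gene-end peak (random median 1593 bp). The medians were 2972.5 bp for excitatory neuron genes (percentile 100), 2946 bp for synaptic adhesion genes (100), 2819 bp for upper-layer genes (99.97) and 2503.5 bp for late activity-response genes (99.9). Wide gene-end peaks were not particular to these lists. Clustered protocadherin genes (3313 bp, percentile 100, with shared peaks), AMPA and kainate receptor genes (2749 bp, 97.95), chromatin architecture genes (2369.5 bp, 99.6) and potassium channel genes (2351 bp, 99.9) also lay above the central 95%. Deep-layer genes (2158 bp, percentile 93.7), inhibitory neuron genes (1911.5 bp, 87.8) and housekeeping genes (1980 bp, 96.0) lay inside the central 95%, and so did GABA-A receptor genes (2134 bp, 82.6), astrocyte genes (1487 bp, 28.6), oligodendrocyte genes (1111 bp, 5.28), endothelial genes (1269 bp, 8.90) and genes of the ribosomal prefix (1665 bp, 63.5). At the other end, gene-end peaks were narrow for microglia genes (662 bp, percentile 0.19), fibroblast and pericyte genes (764 bp, 0.10), muscle genes (937 bp, 1.81), keratin prefix genes (885 bp, 0.16), vomeronasal receptor genes (775 bp, 0.080) and olfactory receptor genes (514.5 bp, 0).

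Further gene families were compared in the same way, on the share with a gene-end peak and on peaks per gene. Of 69 clustered histone genes, which supply histones in dividing cells, 63 had a gene-end peak (percentile 100, random median 15.9%), and their median of 3 peaks per gene was at percentile 100. That random median is far below the 63.7% of all protein-coding genes, so genes of matched length were a peak-poor comparison. Whether neighbouring histone genes share peaks was not examined. Ephrin and Eph receptor genes lay above the central 95% on both measures, with 21 of 22 (99.5) and a median of 5 peaks (98.3), although the latter was inside (97.2) with random lists matched in 100 bins of gene length. Zinc finger genes named Zfp did so for the share, 332 of 397 (100), and not for peaks per gene (percentile 48.1). For 4 families peaks per gene lay above the central 95% and the share lay inside it. The 4 teneurin genes had a median of 54 peaks (percentile 100) and a share at percentile 34.4. Among the 7 Dlgap and Shank scaffold genes the median was 17 peaks (99.7) and the share lay at 59.7. With so few genes and random medians of 75% for teneurin and 85.7% for Dlgap and Shank genes, the share had little room above. The 8 metabotropic glutamate receptor genes had a median of 14 peaks (98.9). All had a gene-end peak, the highest share possible, and as this lay at 93.4 no call above was possible for the share. For the 20 semaphorin genes, which guide axons, the median was 6 peaks (99.0) and the share lay at 83.4. Deciles hold genes of very unequal length at the long end, and with 100 bins the random median for teneurin genes was 25.5 peaks in place of 10. Peaks per gene then lay at 99.7 for teneurin, 98.1 for Dlgap and Shank and 98.6 for semaphorin genes, and inside the central 95% (71.1) for metabotropic glutamate receptor genes. Voltage-gated sodium channel genes (52.2 and 25.5), calcium channel alpha-1 genes (39.2 and 65.8) and nuclear receptor genes (63.1 and 96.5) lay inside on both. Defensin genes had a gene-end peak in 2 of 71 cases (percentile 0) and interferon and interleukin genes in 15 of 58 (0.0050), with peaks per gene inside (17.2 and 37.7). The defensin median of 0 peaks is the lowest possible, so a call below was not possible on that measure. UDP-glucuronosyltransferase genes had 10 of 21 (0.685), with peaks per gene at 13.9. Of those 10, 9 were Ugt1a genes that share the 53.8-kb peak on chromosome 1, and without the Ugt1a genes the count was 1 of 12 (percentile 0), with peaks per gene at 0.025.

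Some stretches without peaks hold genes of unrelated kinds. Among 147 stretches of at least 100 kb without a listed peak that contained 6 or more named protein-coding genes whole, 10 held genes of which at least 75% shared the first 3 letters of their symbol with no other gene there. These held 83 genes over 4041 kb. The one with the most genes lies on chromosome 19 from 6155583 to 6839289, with 14 genes, among them Nrxn2, the splicing factor gene Sf1 and the menin gene Men1. Others lie on chromosome 16 from 17987020 to 18497959 (Dgcr8, Ranbp1 and Comt) and on chromosome 8 from 70674094 to 70856646 (Jund and Rab3a). Whether peaks of these stretches were left out of the list used here, or reads there aligned to patch scaffolds of the assembly instead, is not known. The patch scaffolds carried 43 peaks on 21 sequences. Nrxn2 of the synaptic adhesion list and Pygm of the muscle list lie in such a stretch and count as having no peak. Stretches under the 75% limit can hold unrelated genes too. Trem2 of the microglia list lies in one of 670 kb on chromosome 17 that also holds Nfya, where 45.5% of genes met the rule. Stretches with fewer than 6 whole genes were not counted, so the extent of such doubtful regions is not known. Rims1, with a length of 520187 bp on chromosome 1, also had no peak within 10 kb. The same doubt holds for Egr2, so that absence at these genes is no measure of closed chromatin.

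The order of the peaks in the list was not genomic and went with their position relative to genes. Among the first 8992 peaks of the list 34.7% of peaks lay at a gene end and the median width was 771 bp. Among the last 8992 peaks 6.32% did, and the median width was 647 bp.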
